A study of Mus musculus with 2 samples.

How the data were processed

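Distal colon adenomas of Apcmin mice with an LSL-mTERT allele were dissociated to single cells and profiled on the 10x Genomics droplet platform, with 1 library of G0+T and 1 of G4+T, per the labels. Reads were processed with Cell Ranger 2.1.1 and Seurat against mm10, per the submitters' processing notes. Aligner settings, the annotation release and the filters on cells and genes are not given in the sources used here, nor is any treatment of doublets or free RNA.

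The authors deposited 1 matrix for both libraries, a CIN class per cell, a cell type per cell and an epithelial subtype per epithelial cell. The matrix values are on the natural log scale, as the deposited numbers themselves show: the exponential minus 1 summed to 10000 in every cell, so a value is ln(1 + UMIs per 10000). Divided by the smallest non-zero value of the cell, 100% of the non-zero values were whole numbers within a tolerance of 0.01, and these were taken as the UMI counts of the cell. The class file gives 1 class per library, as set out in the report. The barcode suffixes 1 and 2 match the numbers in the sample titles, whereas the prefix shared by all 14097 cell names matches only the first title; 11 barcodes occurred under both suffixes. Because these labels conflict, no cell was given to G0+T or G4+T, and expression of Tert or any other gene was not used to decide it.

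The design fixed before the data were examined compared G4+T with G0+T, and CIN with non-CIN cells within a library. The first was run as CIN_high against CIN_low. The second, with the share of CIN cells per library and per cell type, could not be run because no library held both classes. The design expected counts; for a log-normalised file it foresaw linear values averaged over cells, so a gene's level is the mean over cells of UMIs per 10000 and its ratio is that of the 2 means, although UMIs could then be recovered. A side with 0 UMIs was set to a floor of 3 UMIs. Counting intervals come from summed UMIs (exact conditional binomial) and from cell numbers (Clopper-Pearson), at 95%. A list median's interval, used to judge the alternatives, comes from resampled UMI sums. All cover counting error only, and no p-value was computed from cells.

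Expression was compared in types with at least 50 cells in each library: epithelial, endothelial, myeloid, pericyte, and T and NK cells. Fibroblasts, B cells and cells of unknown type fell short. Named genes were the 12 epithelial genes (3 in other types) with the largest log2 ratio each way, among genes with a UMI in at least 10% of cells and at least 0.5 UMIs per 10000 on the higher side and 30 UMIs in all; predicted genes, receptor segments, hemoglobin, mitochondrial, ribosomal and sex-linked check genes were left out, and 10 genes of interest were always given. The 40 gene lists were fixed before the data were examined. A member counted as measured with a UMI in at least 2% of cells of 1 side, and as higher or lower at 1.5-fold. A list's median was placed among 10000 random lists of the same size, matched in 50 bins of mean expression, as a description of these libraries.

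Doublets were called with Scrublet in Scanpy 1.11.5 at an expected rate of 6%, per library; it marked 142 cells (2.29%) and 249 cells (3.15%), which stayed in the main values and were left out as an alternative. Chromosomes and coordinates were taken from the GENCODE annotation of mm10 for 98.2% of the genes. For spread between cells, epithelial cells were thinned to 5000 UMIs on autosomal genes without mitochondrial and ribosomal protein genes. Variance over binomial variance was compared with 100 random partitions of the genes into sets of the same sizes, and shifts of the proximal or distal part of a chromosome (split at the median gene) with 50. Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and SciPy 1.17.1, and plots matplotlib 3.10.9.

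The functions were tested on simulated epithelial cells with 200 of the measured genes changed (13474 genes in the step). Genes changed by 2-fold and 4-fold passed the 1.5-fold line in 100% of cases, genes changed by exactly 1.5-fold in 38.8%, and unchanged genes in 2.61%. In simulated cells with chromosome 7 at 1.5-fold in 10% of the cells, 98.7% of the altered and 0.0730% of the other cells passed the line of 0.2. The simulated counts were drawn from 1 pooled epithelial profile, without subtypes or genes that vary together. The 0.0730% is therefore not the rate at which unaltered real cells pass the line. In the real epithelial cells chromosome 18 passed it in 6.60% (CIN_high) and 6.73% (CIN_low). Alternatives were tried for the cells counted, the scaling, the subtype mix, depth, doublets and list membership. The standardised subtype mix weighted only subtypes found in both libraries. It thus left out the 25 Igfbp-positive cells of the CIN_high library, and its S100a8 subtype held 8 CIN_high cells.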

Results

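Single-cell RNA sequencing was carried out on cell suspensions from distal colon adenomas of 25-week-old Apcmin mice that carried an inducible mouse Tert allele. Apcmin mice inherit a truncated copy of Apc, the brake on Wnt signalling, and form intestinal adenomas. The study names 2 groups, G0+T and G4+T, with 1 library each, and its title concerns chromosomal instability that starts at telomeres and signals passed between neighbouring cells. The deposited matrix held 14097 cells and 21041 genes, and the authors' annotation put each cell in a class, CIN_high or CIN_low. Every one of the 6189 cells with the first barcode suffix was CIN_high and every one of the 7908 cells with the second was CIN_low, so the class separated 2 libraries and not cells within a library. The suffix numbers match the numbers in the sample titles, but all cell names begin with a prefix that matches only the first title. Because these labels conflict, the comparisons set the CIN_high library against the CIN_low library and neither is assigned to G0+T or G4+T. With 1 library per class there was no replicate check and no test across animals. Intervals are exact 95% intervals for counting error only, those beside a gene's ratio belong to the ratio of summed UMIs, and a difference between the libraries can be one between mice, tissue pieces or preparations.

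The libraries held 51868113 UMIs (CIN_high) and 74733715 UMIs (CIN_low). The median depth was 6448 UMIs per cell in the CIN_high library and 7154 in the CIN_low library, and 14032.5 and 15364 UMIs in epithelial cells. Cells held between 801 and 109676 UMIs and between 281 and 9007 detected genes. Mitochondrial transcripts took a median of 12.02% of the UMIs of CIN_high and 10.3% of those of CIN_low epithelial cells. Dissociation stress genes in epithelium had a median log2 ratio of -0.25 (CIN_high over CIN_low), with 3 of 16 lower by at least 1.5-fold and 0 higher, among them Hspa1a at 1.73-fold. The median of these genes was 0.19 in endothelial cells and 0.45 in pericytes (5 of 16 higher, 1 lower). It was -0.31 in T and NK cells (4 of 15 lower, 0 higher) and -0.31 in myeloid cells, where the median over all genes was 0.22.

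The first comparison asked how the cell types of the adenomas differed. Fibroblasts made up 15.6% of the CIN_high library (966 cells, 14.7% to 16.5%) and 0.266% of the CIN_low library (21 cells, 0.164% to 0.406%), a 58.8-fold difference in share. Endothelial cells were 3.11-fold more frequent in the CIN_high library, at 9.73% (9.0% to 10.5%) against 3.12% (2.75% to 3.53%), and pericytes 1.83-fold, at 1.34% against 0.733%. Myeloid cells made up 47.3% of the CIN_high library (46.1% to 48.6%) and 67.6% of the CIN_low library (66.6% to 68.7%). T and NK cells were at 3.78% and 5.24%, and B cells at 0.646% and 1.18%. The epithelial share was 21.3% (20.2% to 22.3%) in the CIN_high library and 21.8% (20.9% to 22.7%) in the CIN_low library, a difference within the counting intervals. With immune cells left out of the denominator, epithelial cells made up 44.1% of the CIN_high and 84.0% of the CIN_low library. Fibroblasts then made up 32.4% and 1.02%, a 31.6-fold difference. On that base endothelial cells were at 20.2% and 12.03%, a 1.68-fold difference, and pericytes at 2.78% (2.22% to 3.44%) and 2.83% (2.15% to 3.64%), a difference within the counting intervals. The shares depend on how each piece of tissue was cut and dissociated, which 1 library per class cannot show.

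**Figure D1:**
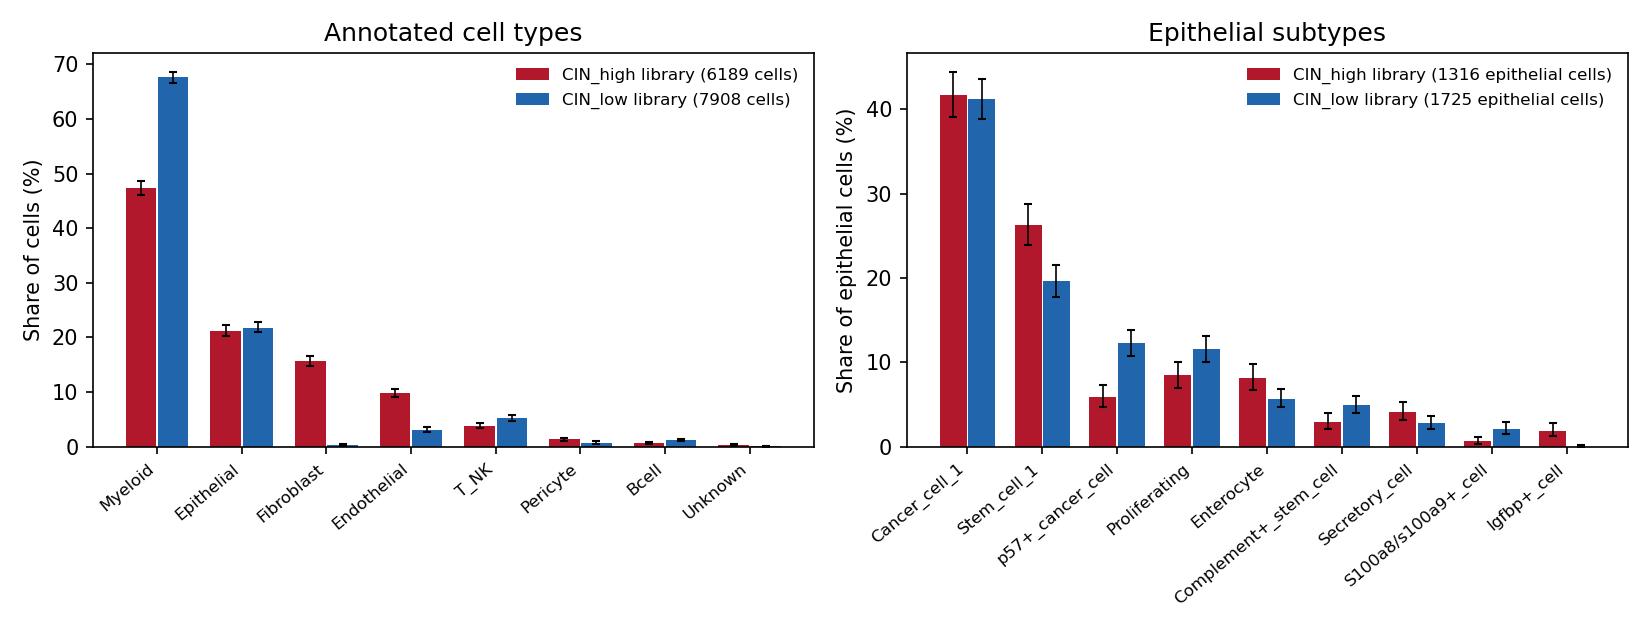
Share of cells (%) per annotated cell type (left) and of epithelial cells per epithelial subtype (right) in the CIN_high library (red) and the CIN_low library (blue), with exact 95% counting intervals as error bars. Fibroblasts stood at 15.6% against 0.266% of cells and myeloid cells at 47.3% against 67.6%, while the largest epithelial subtype stood at 41.7% and 41.2% of epithelial cells.

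Within the epithelium, the authors' largest subtype, Cancer_cell_1, took 41.7% (39.0% to 44.4%) of CIN_high and 41.2% (38.8% to 43.5%) of CIN_low epithelial cells. Cells annotated Stem_cell_1 were more frequent in the CIN_high library, at 26.3% (23.9% to 28.8%) against 19.6% (17.7% to 21.5%). Cells named for p57, a cell cycle inhibitor, were less frequent there, at 5.85% (4.64% to 7.26%) against 12.2% (10.7% to 13.9%), and so were proliferating cells, at 8.43% (6.99% to 10.1%) against 11.5% (10.1% to 13.1%). Enterocytes were at 8.13% and 5.68%, secretory cells at 4.10% and 2.78%, and complement-positive stem cells at 2.96% and 4.93%. The Igfbp-positive subtype held 25 cells of the CIN_high library and 0 of 1725 epithelial cells of the CIN_low library, which allows a share of up to 0.174% by 3 counts of the total (0.214% by the exact interval). The subtype named for S100a8 and S100a9 held 0.608% and 2.09%. S100a8 stood at 3.42 and 17.0 UMIs per 10000 in endothelial cells.

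Target genes of p53, the transcription factor that answers DNA damage, were higher in CIN_high epithelial cells. Of 24 measured targets, 10 were at least 1.5-fold higher, 0 were lower by that much and 23 had a ratio above 1. The median log2 ratio was 0.53, above all 10000 random lists matched on expression. Ccng1, a cyclin G induced by p53, was at 1.38 UMIs per 10000 in CIN_high and 0.536 in CIN_low epithelial cells, 2.57-fold higher (log2 1.36, 2.39 to 2.68 from summed UMIs). Phlda3, an inhibitor of Akt, was 2.49-fold higher, Eda2r 3.12-fold, Ddit4l 3.21-fold and Cdkn1a, which encodes the cell cycle inhibitor p21, 1.78-fold (4.90 against 2.76). Mdm2, the ubiquitin ligase that restrains p53, was 1.39-fold higher, under the 1.5-fold line, and Fas was lower at a ratio of 0.687. The list's median was 0.68 in Cancer_cell_1, 0.74 in Stem_cell_1, 0.60 in enterocytes, 0.37 in proliferating cells and 0.14 in the p57-positive subtype. It was -0.027 in endothelial cells, 0.041 in myeloid cells (-0.18 relative to the median over all myeloid genes), 0.38 in pericytes and 0.25 in T and NK cells. Among the random lists of each type these medians lay at percentiles of 55.6, 1.40, 97.3 and 98.9 in the same order. These differences between cell types were not tested. Ccng1 lies on chromosome 11 (40748552 to 40755311, mm10), Cdkn1a on chromosome 17 (29090976 to 29100727) and Phlda3 on chromosome 1 (135766119 to 135769136), all annotated as protein-coding.

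**Figure D2:**
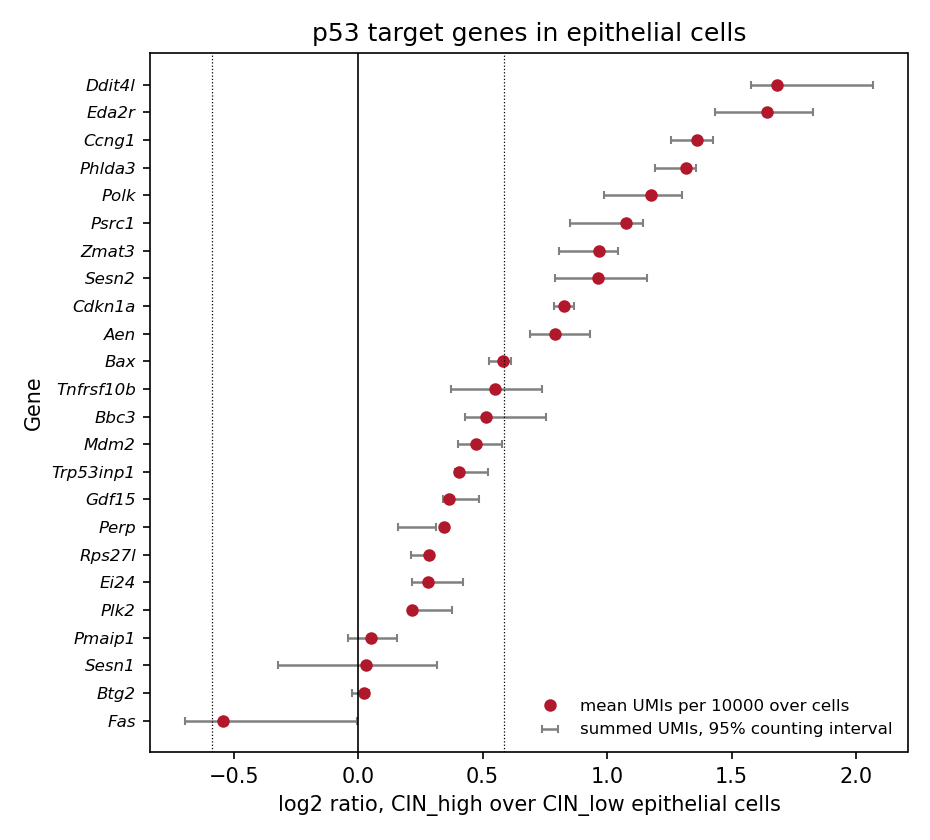
Log2 ratio of CIN_high over CIN_low epithelial cells (horizontal axis) for the 24 measured p53 target genes, from mean UMIs per 10000 over cells (red points) and from summed UMIs with exact 95% counting intervals (grey bars); dotted lines mark a ratio of 1.5 either way. The points run from -0.54 for Fas to 1.68 for Ddit4l, and 23 of 24 lie above 0.

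Cell cycle genes were lower in CIN_high epithelium. Of 20 measured G2 and M phase genes 12 were at least 1.5-fold lower and 0 higher, with a median log2 ratio of -0.61, below all 10000 random lists. Kif11, a spindle motor, was 1.69-fold lower, the checkpoint kinase gene Bub1b 1.68-fold and Aurkb 1.66-fold. Among 20 S phase genes 4 were lower and 0 higher (median -0.43), with Ung at 1.84-fold and Hells at 1.72-fold, and among 17 genes of the mitotic checkpoint and chromosome segregation 5 were lower and 0 higher (median -0.46), with Espl1, the gene of separase, at 2.15-fold. The G2 and M median was -0.25 within proliferating cells, -0.55 in Cancer_cell_1, -1.28 in enterocytes and 1.27 in secretory cells. Over all epithelial cells it was -0.076 once the annotated proliferating cells, which were fewer in the CIN_high library, were left out, and -0.31 with the subtype mix standardised. The standardised medians were -0.29 for S phase genes and -0.26 for mitotic checkpoint genes. The median over all measured genes was itself -0.10.

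Secretory and absorptive marker lists had medians above 0 in CIN_high epithelium. Of 11 goblet cell genes 5 were higher and 1 lower (median 0.36). Muc2, the main mucin of the colon, was 3.63-fold higher (3.31 against 0.910 UMIs per 10000, 4.19 to 4.66), Spink4 2.52-fold (2.93 to 3.08) and Atoh1, the secretory lineage factor, 2.46-fold (60 and 21 UMIs, 2.54 to 7.35). The goblet cell lectin Zg16 was 3.06-fold lower by the mean over cells and 1.29-fold to 1.56-fold lower by summed UMIs. Among 9 deep crypt secretory or Paneth-like genes 3 were higher and 0 lower (median 0.52), with Reg4 at 2.25-fold and the defensin Defa24 at 1.31 and 0.0145 UMIs per 10000. Of 12 colonocyte genes 4 were higher and 1 lower (median 0.37), with Saa1 at 1.61-fold, Ceacam1 at 1.59-fold and Guca2b 1.63-fold lower. Each of these medians lay above all random lists. The CIN_high library also held the larger shares of secretory cells and enterocytes, and with the subtype mix standardised the medians were 0.12 for goblet cell, 0.090 for deep crypt and 0.027 for colonocyte genes. Muc2 lies on chromosome 7 (141690340 to 141754693, mm10).

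Fetal-like and regenerative genes and the interferon response had medians above 0 over all CIN_high epithelial cells, but not in every subtype. Of 19 fetal-like genes 5 were higher and 0 lower (median 0.27). Ereg, an EGF receptor ligand, was 4.96-fold higher at low levels (92 and 14 UMIs, 5.53 to 18.6), Gja1 2.69-fold, Msln 1.90-fold and Clu, a marker of revival stem cells, 1.77-fold (3.36 against 1.90 UMIs per 10000). Within subtypes the list's median was 0.088 in Cancer_cell_1, 0.077 in Stem_cell_1 and 0.017 in enterocytes. It was below 0 in proliferating (-0.15), complement-positive stem (-0.12), secretory (-0.075) and p57-positive cells (-0.046). Of 22 type I interferon response genes 3 were higher and 0 lower (median 0.27), with the transcription factor gene Irf7 at 1.92-fold, Ifi44 at 1.63-fold and Ifit3b at 1.58-fold. That median was 0.34 in Cancer_cell_1 and 0.33 in Stem_cell_1, but -0.48 in enterocytes and -0.40 in the p57-positive subtype, and these differences were not tested. Both lists' medians over all epithelial cells lay above all random lists and stood at 0.18 with the subtype mix standardised. Genes of the DNA sensing pathway had a median of -0.46, with 1 of 7 lower by 1.5-fold (Ifi203). Antigen presentation genes had a median of -0.24 for both MHC class I and class II, with 0 of 13 and 0 of 8 past 1.5-fold.

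Few Wnt target genes and crypt base stem cell markers differed by 1.5-fold. Of 22 Wnt target genes 1 was higher (Cdx2) and 2 were lower (Lef1, Prox1), with a median of -0.12, and of 16 crypt base stem cell markers 1 was higher (Clca4b) and 1 lower (Msi1), with a median of -0.081. The median over all genes was -0.097. Lgr5, the stem cell receptor, was 1.40-fold higher, and Axin2, a direct Wnt target, stood at 2.22 and 2.36 UMIs per 10000. Of 7 measured secreted and surface Wnt antagonists 1 was higher and 2 were lower. Their median was -0.25 (-0.040 with the subtype mix standardised) and their mean log2 ratio 0.66. The secreted antagonists Notum, Wif1, Dkk2 and Dkk3 had log2 ratios of -0.25, -0.37, 0.053 and -0.64, and the membrane-bound antagonist Apcdd1 was 2.53-fold lower. Apc stood at 1.34 and 1.31 UMIs per 10000 (ratio of summed UMIs 0.961 to 1.06). Tert, the catalytic subunit of telomerase, had a UMI in 76 of 1725 CIN_low epithelial cells (4.41%, 3.49% to 5.48%) and in 0 of 1316 CIN_high epithelial cells. That count allows a share of cells with a UMI of up to 0.228% by 3 counts of the total (0.280% by the exact interval). With the CIN_high side set to the floor of 3 UMIs the mean level over cells was 20.7-fold lower in CIN_high epithelium, and the exact interval of the summed UMIs reached down to 14.3-fold. In the CIN_low library a Tert UMI was also found in 4 of 5348 myeloid cells (0.0748%, median depth 6171 UMIs), 1 of 414 T and NK cells (0.242%, 3666 UMIs), 1 of 93 B cells (1.08%, 0.0272% to 5.85%, 6203 UMIs) and 2 of 21 fibroblasts (9.52%, 1.17% to 30.4%, 10762 UMIs). The epithelial cells, at 15364 UMIs, were the deepest, and no Tert UMI was found in any named cell type of the CIN_high library. Telomere maintenance genes had a median of -0.14, with 1 of 15 lower by 1.5-fold (Tert), and DNA repair genes one of -0.21, with 1 of 22 lower (Fancd2, 1.80-fold). Tert lies on chromosome 13 (73626911 to 73649843, mm10) and Apcdd1 on chromosome 18 (62922231 to 62961179).

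Among the other genes named by size, Ptp4a3, a phosphatase, was 2.80-fold higher in CIN_high epithelium, the cornified envelope gene Sprr2a3 2.48-fold, Stox2 2.29-fold, Dcxr 2.06-fold, Atg9b 2.05-fold and the glutathione transferases Gsta3 and Gsta4 2.01-fold and 1.96-fold. Lower were the lipase Pnliprp2 (2.91-fold), the fatty acid desaturase Scd1 (2.88-fold), Smpx (2.69-fold), Snhg11 (2.65-fold), Rdh9 (2.45-fold) and the chemokine Cxcl9 (2.28-fold).

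Neutrophil genes had a median below 0 in every cell type compared. In epithelial cells 8 of 10 were lower in the CIN_high library and 0 higher (median -1.39, and -0.31 with the subtype mix standardised), with G0s2 5.18-fold, Retnlg 3.35-fold, S100a8 2.68-fold and S100a9 2.66-fold lower. Srgn, a proteoglycan of blood cells, was 2.20-fold lower. An S100a8 UMI was found in 38.4% of CIN_high and 88.3% of CIN_low epithelial cells, and in 32.9% and 83.3% of T and NK cells at median depths of 3442 and 3666 UMIs. In pericytes the shares were 33.7% and 82.8%, with mean levels of 7.44 and 7.88 UMIs per 10000 for S100a8 and of 4.15 and 11.7 for S100a9. The S100a8 level was 2.54 and 6.83 UMIs per 10000 in epithelial cells, 6.49 and 15.9 in T and NK cells, which should lack the gene, and 156 and 282 in myeloid cells. Fibroblast genes went the other way in epithelium, with all 7 measured of 11 listed higher in CIN_high cells at low levels (median 3.82). That median was 1.28 with the subtype mix standardised, which leaves out the Igfbp subtype, and 1.38 without the S100a8 and Igfbp subtypes. The fibroblast markers Col1a1 (2.66% and 0.348% of cells), Col3a1 (3.57% and 0.870%) and Dcn (5.93% and 0.986%) passed the 2% line only in the CIN_high library. The count and the size of the median are thus partly set by that line. Dcn stood at 0.279 and 0.00995 UMIs per 10000 in epithelial cells (a ratio of 37.97 to 97.2 from summed UMIs), at 0.261 and 0.0176 in T and NK cells and at 58.1 in CIN_high fibroblasts. In endothelial cells Dcn went the opposite way, at 0.295 and 0.665, and the fibroblast list had a median of -0.73 (1 of 4 higher, 3 lower). In epithelium, secreted factors of the fibroblast signal list moved with the fibroblast genes, 5 of 9 higher and 2 lower (median 1.55, between 0.90 and 2.75 with other UMI minimums for members). Grem1, Bmp4 and Sfrp1 had 104, 92 and 210 UMIs in CIN_high epithelium and 6, 4 and 1 in CIN_low epithelium.

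Inflammatory mediators under NF-kB had medians below 0 in CIN_high cells of the stroma and immune system. In endothelial cells 13 of 22 were lower and 0 higher (median -0.80), in pericytes 12 of 23 were lower and 2 higher (median -0.70), and in T and NK cells 11 of 20 were lower and 1 higher (median -0.78). In myeloid cells 10 of 22 were lower and 0 higher. The median over all genes in myeloid cells was 0.22, and relative to it the list stood at -0.70. The neutrophil attractant Cxcl2 was at 42.5 and 108 UMIs per 10000 in myeloid cells and 6.28-fold lower in endothelial cells, Cxcl3 was 4.28-fold lower in myeloid cells, and Il1a was 8.19-fold lower in endothelial cells. In epithelial cells 8 of 24 were lower and 2 higher (median -0.18), with Cxcl3 4.38-fold lower and Ccl2 1.75-fold higher. The neutrophil list moved the same way, with medians of -2.10 in endothelial cells, -1.11 in pericytes and -1.38 in T and NK cells, and of -0.99 in myeloid cells relative to all genes. Of the markers of macrophages, monocytes and dendritic cells 9 of 12 were lower in endothelial cells (median -1.49), 7 of 10 in pericytes (-1.07, and -1.997 from summed UMIs) and 8 of 11 in T and NK cells (-1.47, and -2.05). Cxcl2 stood at 1.1999 and 7.54 UMIs per 10000 in endothelial cells and at 1.82 and 6.12 in T and NK cells, and Il1a at 0.0530 and 0.434 in the former and 0.117 and 0.291 in the latter. An Il1b UMI was found in 19.4% of CIN_high and 43.7% of CIN_low endothelial cells, and in 16.7% and 45.9% of T and NK cells. Whether the non-myeloid types made less of the mediators or carried less free myeloid RNA was not tested. Nor was it tested whether the lower values in myeloid cells reflect a different mix of neutrophils and macrophages.

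In myeloid cells the largest ratios by the fixed rule were those of Adamdec1 (7.01-fold higher by the mean over cells, 4.15 to 5.06 by summed UMIs), Igfbp4 (2.95-fold, 1.66 to 2.07) and Lpl (2.72-fold, 2.18 to 2.55), and of the neutrophil granule gene Ngp (4.92-fold lower) and the chemokines Ccl3 (4.73-fold) and Ccl4 (4.60-fold). Fibroblast genes were higher there too, all 6 measured of 11 listed, with a median of 3.99 relative to all genes. Col1a1 (2.15% and 0.430% of cells), Col3a1 (3.96% and 0.841%) and Dcn (4.64% and 0.972%) passed the 2% line there only in the CIN_high library, so the count is partly set by that line. In lymphocytes Adamdec1 stood at 0.0799 and 0.0107 UMIs per 10000, against 0.762 and 0.109 in myeloid cells, and Igfbp4 at 0.392 and 0.121, against 0.524 and 0.178. Macrophage, monocyte and dendritic cell markers had a median of 0.14 in myeloid cells relative to all genes, and 2 of 14 were higher, Xcr1 of conventional dendritic cells at 3.22-fold and Flt3 at 1.68-fold. A UMI of the macrophage gene C1qa was found in 46.8% of CIN_high and 40.6% of CIN_low myeloid cells. For the neutrophil gene Csf3r the shares were 34.1% and 42.1%, at mean levels of 2.84 and 2.34 UMIs per 10000. Whether the ratios in myeloid cells reflect a different mix of these cells was not tested. In endothelial cells the soluble guanylate cyclase genes Gucy1b1 and Gucy1a1 were 16.2-fold and 10.5-fold higher and Igfbp5 10.4-fold (5.36 to 7.38), while Ifitm6, Cxcl3 and Ptn were 11.3-fold, 8.58-fold and 7.64-fold lower. The pericyte markers Rgs5 (0.801 against 0.113 UMIs per 10000), Acta2 (0.244 against 0.0204) and Myh11 (0.0711 against 0.00230) were also higher in CIN_high endothelial cells. In pericytes Hhip, an inhibitor of hedgehog signalling, had 388 UMIs in the CIN_high and 0 in the CIN_low library, 166-fold higher against the floor of 3 UMIs by the mean over cells (interval of summed UMIs from 118-fold). Adamdec1, with 0 UMIs in CIN_low pericytes, was 149-fold higher against that floor (from 107-fold), and Bdkrb2 had 85 and 2 UMIs (ratio 12.9 to 402). Tbx20 had 1 UMI in CIN_high and 31 in CIN_low pericytes (4.59-fold to 1122-fold lower), Cxcl5 was 19.6-fold lower and Saa3 15.4-fold. In T and NK cells Lmo4, Pibf1 and Gadd45g were 4.07-fold, 3.66-fold (1.38 to 3.88) and 2.95-fold higher, and Ccl3, Lcn2 and Ccl4 were 21.2-fold, 5.18-fold and 4.55-fold lower. Checkpoint genes had a median of -0.37 there, with 2 of 9 lower, Tigit 2.72-fold and Havcr2 2.13-fold. T or NK cell markers themselves had a median of -0.69, with 9 of 14 lower and 1 higher: Trac stood at 2.79 and 5.19 UMIs per 10000 and Cd3d at 5.47 and 8.80, and the NK receptor gene Ncr1 at 0.908 and 0.376. Pericytes numbered 83 and 58, and their markers differed too: Myh11 stood at 25.7 and 6.07, Acta2 at 43.0 and 17.8 and Rgs5 at 55.9 and 116 UMIs per 10000, with an Rgs5 UMI in 69.9% and 98.3% of cells. In CIN_low myeloid cells Lcn2 stood at 26.7, Cxcl3 at 18.4, Ifitm6 at 7.20 and Ccl3 at 7.35 UMIs per 10000. Whether the lower values of these genes in other types reflect free myeloid RNA was not tested.

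The last comparison set chromosomes side by side in the epithelium. Median log2 ratios of genes on each chromosome, relative to all genes, lay between -0.062 (X) and 0.082 (chromosome 11). In endothelial cells X was lowest (-0.089) and chromosome 11 highest (0.053) too. The range was -0.087 to 0.127 in T and NK cells and -0.033 to 0.024 in myeloid cells. At 5000 UMIs per cell, the share of a cell's detected genes that lie on chromosome 7 was over 0.2 (log2) above the library's median cell in 9.49% of 1106 CIN_high epithelial cells (7.83% to 11.4%) and in 1.11% of 1530 CIN_low epithelial cells (0.649% to 1.77%). For chromosome 8 the shares were 7.96% (6.43% to 9.71%) and 2.35% (1.65% to 3.24%), and for chromosome 11 they were 7.14% (5.70% to 8.82%) and 0.523% (0.226% to 1.03%). At least 1 of these chromosomes was past that line in 23.1% of CIN_high cells (20.6% to 25.7%) and 3.92% of CIN_low cells (3.01% to 5.02%). Chromosomes 7 and 8 were both past it in 2 CIN_high cells, 7 and 11 in 9, and 8 and 11 in 6. Over all 19 autosomes at least 1 was past the line in 55.7% (52.7% to 58.7%) and 38.4% (35.99% to 40.9%) of cells, and over the 16 other than 7, 8 and 11 in 40.9% (37.95% to 43.8%) and 35.4% (33.03% to 37.9%). Chromosome 18 was past it in 6.60% (5.21% to 8.23%) and 6.73% (5.53% to 8.11%), a difference within the counting intervals. In the p57-positive subtype the shares for chromosome 8 were 9.52% (3.58% to 19.6%) and 9.73% (5.87% to 14.9%), a difference within the counting intervals. For chromosome 9 the order was the opposite, at 0.904% (0.434% to 1.66%) and 4.25% (3.29% to 5.38%). The line, the measure and these chromosomes were chosen after the values had been seen, and 210 CIN_high and 195 CIN_low epithelial cells were too shallow to enter.

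**Figure D3:**
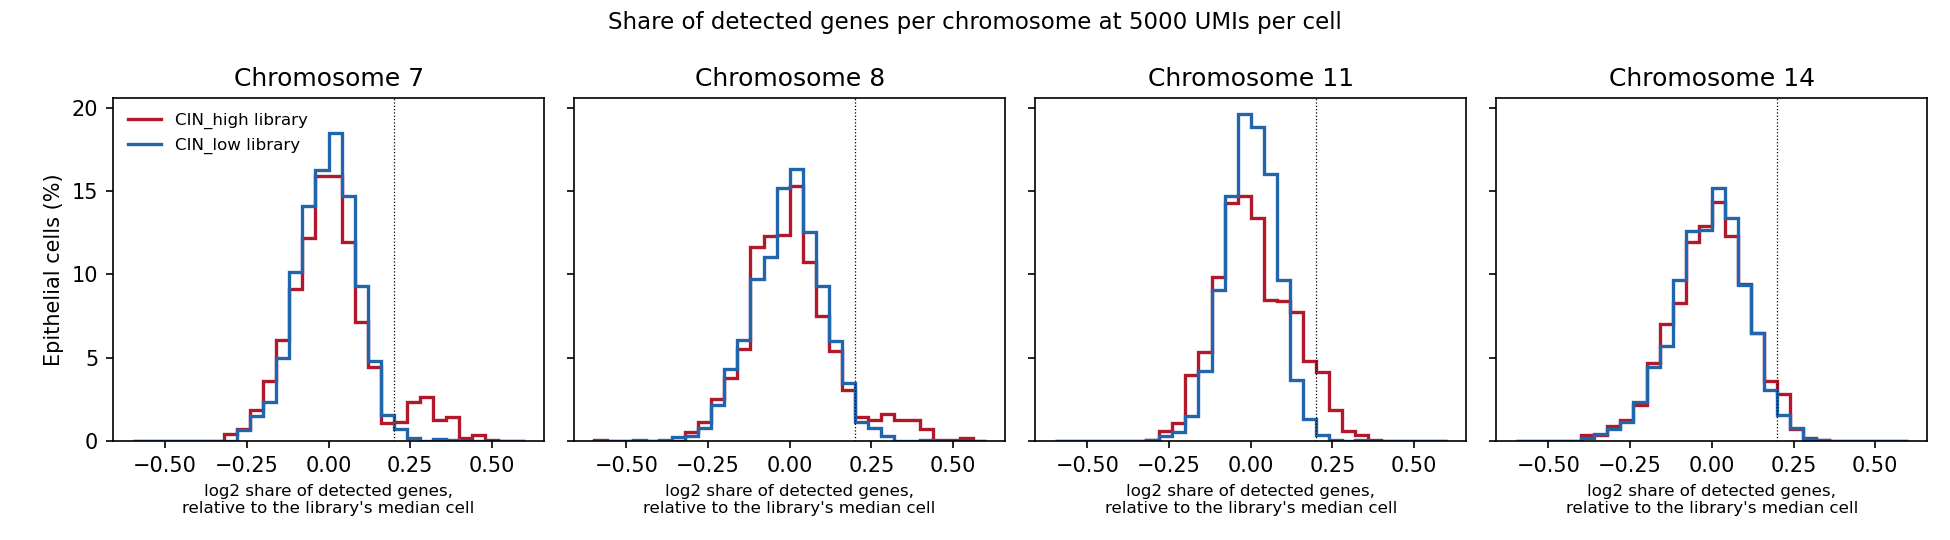
Distribution over epithelial cells (% of cells, vertical axis) of the share of detected genes on chromosomes 7, 8, 11 and 14, as log2 relative to the library's median cell (horizontal axis), in the CIN_high (red) and CIN_low (blue) libraries at 5000 UMIs per cell; the dotted line marks 0.2 and values beyond the axis are counted in its end bins. For chromosome 7, 9.49% of CIN_high and 1.11% of CIN_low cells lie right of the line, and for chromosome 14, shown as a reference, 3.80% and 2.55% do.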

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

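The tests of free RNA, of normal mucosa, shallow cells and connective tissue, and of chromosomes by detected genes, by subtype, by cell type and by the proximal and distal parts of chromosomes 7 and 8 alone were chosen only after the result was seen.

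Fetal-like and regenerative genes had a median log2 ratio of 0.27 in epithelial cells and of -0.45 in endothelial cells, a difference of 0.71, and of -0.37 in T and NK cells, a difference of 0.64. Colonocyte genes stood at 0.37 in epithelial and -0.62 in endothelial cells, a difference of 0.99, and fibroblast genes at 3.82 in epithelial cells and -0.70 in pericytes, a difference of 4.51. The fibroblast medians rest on 7 measured members in epithelium and on 11 in pericytes, and members in epithelium were kept in part through their CIN_high level. With the epithelial subtype mix standardised, the epithelial medians were 0.18, 0.027 and 1.28 for fetal-like, colonocyte and fibroblast genes. These lists stood out because they went opposite ways in 2 cell types: their epithelial medians lay above all random lists and the others at percentiles of 0.14, 0.88, 0.37 and 0.34 in the order given. The differences were not tested.

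The p53 targets that were higher in CIN_high epithelium kept a median log2 ratio of 0.56 with the subtype mix standardised and of 0.48 with every cell thinned to 5000 UMIs, against 0.53 unadjusted. Neither a shift between subtypes nor depth therefore accounts for the whole pattern. Of the 10 members past 1.5-fold, 9 gained at least 2 times as many UMIs per 10000 in epithelial cells as in lymphocytes, which argues against free RNA for those 9. The 10 were picked by their rise in epithelium, and a fall in lymphocytes was counted as no gain. The other 14 members were not examined, so the count does not exclude free RNA for the list. With 1 library per class, a difference between mice unrelated to the class cannot be told apart from one tied to it. The list's median was also above 0 in pericytes (0.38) and in T and NK cells (0.25). It was -0.027 in endothelial cells and -0.18 in myeloid cells relative to all genes. A rise shared by some other cell types of the CIN_high library was not tested. A p53 response tied to the class stays open and was not tested.

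The excess of fibroblasts in the CIN_high library persisted among cells with at least 5000 UMIs, where their share was 70.9-fold higher (39.6 to 138), so a loss of shallow cells does not account for it. Epithelial cells without a UMI of Axin2, Nkd1, Notum and Wif1 were 1.38-fold as frequent in CIN_high as in CIN_low at equal depth (1.09 to 1.75). This lay above an equal share but below the 2-fold excess set as the mark of more normal mucosa, and the bound for excluding it was changed from 2-fold to an equal share after the value was seen, so normal mucosa is neither excluded nor shown. At least 2 of 4 lymphatic markers were found in 19.2% of CIN_high endothelial cells (15.7% to 22.98%) and 8.87% of CIN_low ones (5.34% to 13.7%), so a piece that held more connective tissue of another layer stays open too. A recruitment of fibroblasts tied to the class may account for the pattern too and was not tested.

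The cells with a shifted chromosome were looked for first through UMI sums, as planned, where the excess spread over random gene sets was 1.63-fold larger in CIN_high epithelium but the difference (0.851) was smaller than the random spread (1.27), which decides nothing. A measure on detected genes, added after that result, gave an excess 3.06-fold larger in CIN_high (0.239 and 0.0781), and 3.08-fold within Cancer_cell_1 alone, so the subtype mix does not account for it. In CIN_high cells picked on the proximal or the distal part of chromosome 7 or 8 the other part was shifted by at least 0.147 (log2), beyond every random partition, which argues against a local gene cluster there; over chromosomes 7, 8 and 11 the lowest distal shift was 0.0676, and on chromosome 11 cells picked on the distal part showed -0.013 on the proximal part, so the distal shift alone cannot exclude a gene cluster there. At 2000 UMIs the excess was larger in CIN_high in each other type compared as well, in T and NK cells (2.102-fold, against 2.83-fold in epithelium), myeloid cells (0.0908 against 0.0595), endothelial cells (0.105 against 0.0699) and pericytes (0.143 against 0.0875), by under 2 SD of the random partitions in the last 3, but at 5000 UMIs the myeloid gap (0.0831 against 0.0452, random SDs 0.00669 and 0.00837) was beyond 2 SD, so part of the spread may belong to the library. By chromosome, the myeloid excess at 5000 UMIs was 0.583 in CIN_high and 0.0549 in CIN_low on chromosome 6. On chromosomes 7, 8 and 11 it was 0.106, 0.106 and 0.0745 in CIN_high and 0.179, 0.113 and 0.0530 in CIN_low. The myeloid gap therefore does not account for the spread of chromosomes 7 and 8, and the T and NK gap was not split by chromosome. Chromosome 6 also passed the test of both parts in CIN_high epithelium, with shifts of 0.0927 and 0.0750. Its excess at 5000 UMIs was 0.273 there, smaller than in myeloid cells of the same library, so passing that test does not by itself show a gain. Gains of chromosomes 7 and 8 in separate cell populations are a hypothesis, which DNA from the same tissue could test.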

How the results depend on the processing

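The alternatives with summed UMIs, without doublets, at 5000 UMIs per cell, and without the S100a8 and Igfbp subtypes or proliferating cells were chosen after seeing the data. Of 1303 list medians under an alternative, 1219 kept their sign, 1016 stayed within the counting interval, and 3 that were at least 1.5-fold from no change turned to the other sign; of 484 values for named genes 480 kept their sign and 330 stayed within it, and of 78 shares 62 stayed. With immune cells out of the denominator the epithelial share was 44.1% in CIN_high and 84.0% in CIN_low and the fibroblast share 32.4% and 1.02%, by construction. Scaled by the median ratio over genes, the medians in epithelium were 0.63 for p53 targets, 0.36 for fetal-like genes, 0.36 for interferon genes and -0.51 for G2 and M genes. As differences of mean natural-log values they were 0.10, 0.026, 0.029 and -0.029 in the same order, a scale on which low genes give small numbers. With the subtype mix standardised they were 0.18 for fetal-like genes, 0.18 for interferon genes and -0.31 for G2 and M genes. Summed UMIs gave 0.39 for interferon genes. The G2 and M median was -0.65 without the S100a8 and Igfbp subtypes and -0.076 without proliferating cells; the cause of these shifts was not tested.

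The 3 that turned were stem cell markers in endothelial cells (0.41 from summed UMIs), checkpoint genes in pericytes (-0.00601 as a natural-log difference) and goblet cell genes in T and NK cells (0.071 from summed UMIs); the cause was not tested. Not run, because no library held both classes, were the alternatives for CIN against non-CIN cells, for the share of CIN cells, and for each status alone. No paired analysis was possible because each class had 1 library. Depth limits genes such as Tert, with 80 UMIs in CIN_low epithelial cells.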

Other observations

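The description of fibroblast genes and the chromosome tables other than the planned UMI sums were chosen only after the values were seen. Fibroblasts were too few in the CIN_low library for a planned comparison, with 21 cells against 966. In the CIN_high cells the B cell attractant Cxcl13 stood at 25.4 UMIs per 10000, against 0.905 in the 21 CIN_low cells (a ratio of 14.4 to 34.9 from summed UMIs), and Meg3 at 3.18 against 0.206 (5.17 to 30.7). The CIN_low fibroblasts held more of the acute phase gene Saa3 (78.9 against 1.72, a ratio of 44.4 to 51.3 from summed UMIs), of the matrix metalloproteases Mmp13 (36.1 against 0.951, 15.9 to 18.9), Mmp10 (11.8 against 0.419, 11.4 to 15.2) and Mmp3 (6.38 against 0.284, 7.02 to 12.4), and of the hyaluronan-degrading Cemip (6.38 against 0.0579, 18.9 to 35.3). For Mmp13, Mmp10, Mmp3 and Cemip the ratio of the means lay above that interval. In the 21 CIN_low fibroblasts a UMI was found in 52.4% (Saa3), 38.1% (Mmp13), 57.1% (Mmp10), 28.6% (Mmp3) and 33.3% (Cemip) of cells. In CIN_high fibroblasts the shares were 9.01%, 1.24%, 4.14%, 4.04% and 0.414% in the same order. The CIN_low levels thus rest on few cells, a spread that the counting intervals do not cover.

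The 2 CIN_high cells past the line for both chromosomes 7 and 8 compare with 105 past it for chromosome 7 and 88 for chromosome 8. For chromosome 11, 79 cells were past it, 9 of them also for chromosome 7 and 6 also for chromosome 8. The overlap expected of independent chromosomes was not computed, so the small overlap of 7 and 8 does not by itself show separate populations. Over the 19 autosomes, cells picked on either the proximal or the distal part were shifted on the other part by over 0.05 (log2) and beyond every random partition for 3 chromosomes of the CIN_high library (6, 7 and 8) and for 1 of the CIN_low library (9). On chromosome 11, CIN_high cells picked on the genes between positions 78357577 and 101172997 (mm10) were shifted by 0.28 on the genes from there to the end, and CIN_low cells by -0.034. Picked the other way, the shifts were 0.218 in CIN_high and -0.0085 in CIN_low cells. In myeloid cells the excess spread of chromosome 6 was 0.583 in the CIN_high and 0.0549 in the CIN_low library, against 0.273 and 0.00788 in epithelium. The chromosome 7 line was passed by 20.0% of 105 proliferating cells (12.8% to 28.9%), 9.13% of 460 Cancer_cell_1 cells and 1.59% of 63 p57-positive cells of the CIN_high library.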
